A study of Mus musculus with 90 samples.

How the data were processed

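Single-cell RNA libraries were made with SMART-Seq kits from CD41-positive stem cells of mouse bone marrow after culture, per the labels. The authors deposited gene values as TPM, rounded to 1 decimal, in a table of 46 libraries and a table of 33 without outliers. Values of libraries in both tables were identical. Reads were processed with FastQC 0.11.7, cutadapt 1.9.1, STAR 2.6.1e and featureCounts 1.6.2 on mm10, per the submitters' processing notes. The annotation, the strand setting, the step from counts to TPM and the rule for outliers are not given in the sources used here. TPM has the same total in every library, so depth is unknown. The number of genes above 0 is given, though it does not stand for depth or quality. Because every library shares this total, a few very abundant transcripts lower all other values. In a library with few captured molecules many genes are listed at 0, housekeeping genes included.

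Groups were taken from the titles and genotype labels, and columns were matched to samples by the description in the labels, as a few titles are spelled differently. Of 90 labelled samples, 44 were not analysed here, and 1 column of the full table that matched no sample was not used. The table without outliers was the main one. Each library is 1 cell and no label names an animal, donor or culture, so each group counted as 1 sample and no test was run. Values were compared as the difference in mean log2(TPM + 1), with a pseudocount of 1, beside the pooled SD between cells. This scale understates the difference of low genes. Shares of cells with 1 TPM or more have exact Clopper-Pearson 95% intervals, which cover counting error only. Gene positions came from the GENCODE M21 annotation of GRCm38, matched by symbol for 26762 of 35869 symbols. Computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

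Before the data were examined, 25 gene lists were fixed: megakaryocyte-platelet, megakaryocyte transcription factors, platelet genes linked to RUNX1, proplatelet cytoskeleton, granule and trafficking, stem cell, erythroid, granulocyte-monocyte, lymphoid, mast cell and basophil, stromal-endothelial, mitosis, DNA replication, cell cycle brakes with D-type cyclins, interferon response, p53 response, immediate early, TNF, glycolysis, oxidative phosphorylation, ribosome biogenesis, cholesterol synthesis, housekeeping, sex-linked and RUNX family. Some genes stand in more than 1 list, such as Pf4 in the megakaryocyte-platelet and RUNX1-linked lists. The score of a cell is the mean log2(TPM + 1) over members with a mean of 1 TPM or more in a group of the comparison. For lists of 5 or more members, the median difference was ranked among 10000 random lists of the same size matched on mean expression in 20 bins.

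The rule for named genes, also fixed then, took genes with a mean of 10 TPM or more and 1 TPM or more in 50% of cells of a group, a difference larger than the pooled SD, and the same sign within each title prefix with 2 or more cells of both groups, in the full table and in the ratio of mean TPM. The 12 highest and 12 lowest were named, without predicted genes, pseudogenes, mitochondrial and ribosomal protein genes. Up to 4 members per list, those with the largest differences at a mean of 10 TPM or more, were added without the other conditions on cells, SD and sign, and the RUNX family without any. The list members named as examples are a subset of those, picked after their values were seen. Of the genes the rule allows, 2 list members are not reported here.

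Alternatives fixed before the data were examined were the full table, pseudocounts of 0.1 and 10, the ratio of mean TPM, medians over cells, median-ratio rescaling, removal of mitochondrial and ribosomal protein genes, no filter or a minimum of 10 TPM, each title prefix alone, cells with few detected genes left out, and each cell left out in turn. Chosen after seeing the data were 2 more settings, which left libraries with a housekeeping score under 6 out of either table, with the limit also set then. The analysis was tested on simulated data with 200 changed genes, 50 per shift. For shifts of 2, -2, 1 and -1 the mean recovered differences were 1.94, -2.27, 0.90 and -1.22 among 11562 genes for MK against NMK cells in WT. They were 1.91, -1.69, 1.21 and -1.13 among 13365 genes in KO, 1.97, -2.04, 0.92 and -1.10 among 11796 genes for KO against WT in MK cells and 2.12, -1.91, 1.08 and -0.77 among 12835 genes in NMK cells. The share of shifted genes with the right sign was lowest at 78%, for shifts of -1 between KO and WT in NMK cells. Shifts were put only on well-expressed genes, with normal noise and no libraries of low housekeeping score. The recovered values therefore do not cover genes often listed at 0. This test on simulated data was written after the tables had first been analysed.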

Results

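The study asked how loss of RUNX1 changes what blood stem cells become. RUNX1 is a transcription factor of blood development, and germline changes in it cause low platelet counts. Mice carried Runx1 flanked by loxP sites, and the Mx1-Cre recombinase, which poly(I:C) switches on, was present in the knockout (KO) mice and absent in the wild-type (WT) controls. Hematopoietic stem cells bearing CD41, the platelet integrin subunit encoded by Itga2b, were sorted from bone marrow 4 weeks after 4 poly(I:C) injections and cultured for 2 days. Cells that looked like megakaryocytes (MK), the platelet-forming cells, and cells that did not (NMK) were then picked for SMART-Seq libraries, a full-length method for single cells. WT and KO stand below for libraries labelled so.

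The tables analysed held 46 libraries, of which the authors kept 33 in a version without outliers: 9 WT NMK, 6 WT MK, 13 KO NMK and 5 KO MK. A further 44 of the 90 labelled samples were not analysed here. Values were deposited as TPM, a transcript abundance scaled to the same total in every library, which keeps no record of depth, so the number of reads behind each value is unknown. The number of genes above 0 ranged from 14089 to 15252 in WT MK, from 5475 to 11715 in WT NMK, from 11896 to 14487 in KO MK and from 3011 to 10987 in KO NMK libraries. MK libraries thus held more genes than NMK libraries of the same genotype, and the median gene was 0.70 higher in WT MK than in WT NMK cells and 0.59 higher in KO MK than in KO NMK cells on the log2(TPM + 1) scale. For the comparisons of KO with WT the median gene differed by 0.09 in MK and 0.20 in NMK cells. No label names an animal or a culture, so each group counts as 1 sample. Errors are SDs between cells, no p-value is given, and differences are set against the pooled SD between cells. For the 5 WT MK libraries without a title prefix, the same cDNA deposited several times stays open, as described below. If so, the SD of WT MK cells understates the spread between cells.

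Housekeeping genes fell into separate ranges, with a limit of 6 set after seeing the data. The mean log2(TPM + 1) of 14 such genes was 7.43 or higher in 33 of the 46 libraries and 5.78 or lower in the other 13. The authors left out 11 of these 13 and kept 2, both KO NMK. Replicate B1-1b had a score of 3.54 and 91.6% of its TPM on mitochondrial genes, and replicate B1-2a had a score of 2.09 with 3011 genes above 0. Both stand in every KO NMK mean and single gene value below, and list differences without them are given with each comparison that uses KO NMK cells. A low score did not always go with few genes. The left-out KO MK B1-1 held 27999 genes above 0 at a score of 5.78, with 71.5% of its TPM on mitochondrial genes.

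**Figure D1:**
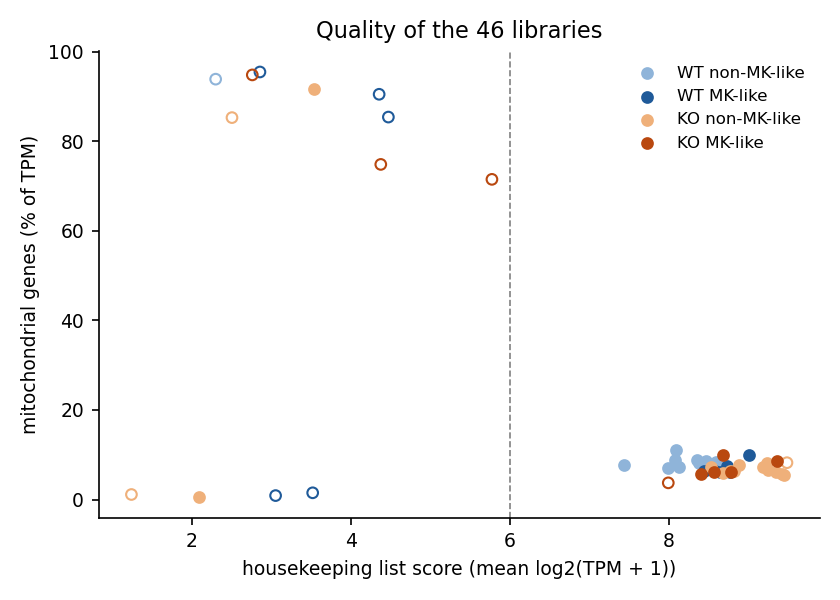
Housekeeping list score (x axis, mean log2(TPM + 1)) against the share of TPM on mitochondrial genes (y axis, %) for 46 libraries. Filled points are the 33 libraries the authors kept, hollow points the 13 they left out, and the dashed line marks a score of 6, with 2 filled KO NMK points below it.

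Runx1 itself was not lower in KO libraries. Runx1 lies on chromosome 16 from 92601466 to 92826149 on the minus strand (GRCm38). Its mean was 22.5 TPM ± 16.6 (SD, n = 5) in KO MK and 12.4 TPM ± 5.53 (SD, n = 6) in WT MK cells, a log2 difference of 0.63 against an SD of 0.77 that was 0.30 without KO MK B1-3. In NMK cells it was 12.1 TPM ± 14.8 (SD, n = 13) in KO and 5.08 TPM ± 5.65 (SD, n = 9) in WT, a log2 difference of 0.48 against an SD of 2.09. This difference was 0.23 without KO NMK B1-5 and 0.76 without WT NMK 2B. At least 1 TPM was seen in 5 of 5 KO MK cells (95% exact binomial interval 47.8 to 100%) and in 7 of 13 KO NMK cells (53.8%, 25.1 to 80.8%). It was seen in 6 of 6 WT MK cells (54.1 to 100%) and in 5 of 9 WT NMK cells (55.6%, 21.2 to 86.3%). These intervals cover counting error only. A value for the whole gene does not isolate the floxed exons, so it cannot check the genotype labels. Among relatives and partners, Runx3 averaged 11.3 TPM ± 8.40 in KO MK against 28.3 TPM ± 16.5 in WT MK cells, a log2 difference of -1.55 against an SD of 1.17. It was 0.5 TPM in KO MK 1A and 7.2 to 22.8 TPM in the other KO MK cells, against 11.5 to 59.6 TPM in WT MK cells. Cbfb, the binding partner of RUNX proteins, differed by -0.05 between the same groups, and the mean of Runx2 was 1.22 TPM or lower in all 4 groups.

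The first comparison asked what sets MK-like apart from other cells when Runx1 is intact. WT MK cells carried platelet transcripts at far higher levels than WT NMK cells. Pf4, which encodes platelet factor 4 (chromosome 5, 90772435 to 90773383), averaged 15807 TPM ± 2581 in WT MK and 334.0 TPM ± 454.1 in WT NMK cells (SD, n = 6 and 9). Across the megakaryocyte-platelet list, 29 of 31 measured members were higher, and the list score was 5.80 ± 0.41 against 2.64 ± 0.37. Its difference of 3.16 exceeded the SD of 0.39, and all 6 MK cells lay above the highest NMK cell. Stem cell genes went the other way, with 17 of 26 members lower.

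Itga2b averaged 147.9 TPM ± 153.1 in MK and 5.29 TPM ± 8.31 in NMK cells. Gp1ba, of the receptor for von Willebrand factor, had a log2 difference of 2.79. The 12 genes with the greatest excess in MK cells were Fcer1g (8.31), Pf4 (7.20), Ppbp (6.96), Tuba8 (6.89), Zswim7 (6.78), Rasl11a (6.69), Sdpr (6.66), Timp3 (6.65), Mrps22 (6.59), Mir8116 (81.1 TPM in MK, listed at 0 in NMK), Ccl2 (6.17) and Gp5 (6.15), as log2 differences except where a group is listed at 0. Mir8116 is a small RNA gene that can share reads with a host transcript, so its value is uncertain. Among 10000 random lists matched on expression, the median of the megakaryocyte-platelet list stood at percentile 100, that of the proplatelet cytoskeleton list at 98.3 and that of the granule list at 91.9, as a description of these libraries.

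The transcription factor list was 1.20 higher (SD 0.36, 17 of 20 members), yet its median stood only at percentile 24.95 of random lists. Within it, Gata1, which drives megakaryocyte and erythroid maturation, averaged 29.3 TPM ± 11.2 in MK cells and was below 1 TPM in all 9 NMK cells, while its cofactor Zfpm1 differed by 2.67. The list of platelet genes linked to RUNX1 was 1.73 higher (SD 0.33, 12 of 13), with a percentile of 17.9 for its median. The cytoskeleton list was 1.49 higher (SD 0.30, 19 of 22), with Tpm4 at 4.41 and Vcl at 3.52. Granule and trafficking genes were 1.18 higher (SD 0.32, 18 of 21), among them Slc35d3 at 4.91 and Rab27b at 3.67.

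Erythroid genes were also higher in WT MK cells, by 1.84 (SD 0.70, 11 of 12 members), with Icam4 at 28.5 TPM in MK, listed at 0 in NMK and the transferrin receptor gene Tfrc at 4.57. The stem cell list was 0.76 lower, a difference of -0.76 against an SD of 0.65, with Hoxa9 at -3.56 and Mycn against the trend at 4.13. Ly6a, which encodes the stem cell antigen Sca-1, was the gene with the greatest deficit in MK cells, at 0.18 TPM ± 0.45 against 319.6 TPM ± 218.7. The other 11 were Rgs2 (-6.76), Gstm1 (-6.75), Ypel3 (-6.21), Plp2 (-5.98), Cd24a (-5.93), Krt18 (-5.52), Ramp1 (-5.39), Lgals1 (-5.27), Nupr1 (-5.11), Ldhb (-4.72) and Vim (-4.70). Granulocyte-monocyte genes differed by -0.29 (SD 1.09, 7 of 8 lower), with Spi1 at -2.94 and Ms4a3 at 5.33. Mast cell and basophil genes were 2.82 higher (SD 1.29, 3 of 4), which includes Fcer1g and Gzmb. The lymphoid list differed by 0.64 (SD 1.25) and the stromal-endothelial list by 0.79 (SD 0.67).

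Growth and metabolic genes were mostly higher in WT MK cells, but so was the median of all 11562 genes with a mean of 1 TPM or more, by 0.70. Among random lists, the medians of the mitosis, oxidative phosphorylation, DNA replication and glycolysis lists stood at percentiles 99.7, 95.7, 91.5 and 90.9, and those of the p53 response, brakes, ribosome biogenesis, housekeeping and cholesterol lists nearer the middle, at 85.5, 84.6, 81.85, 74.5 and 42.5. DNA replication genes differed by 1.13 (SD 0.99, 27 of 29 higher; Ccne2 at 2.97) and mitosis genes by 1.64 (SD 1.71, 25 of 28; Ccnb2 at 4.39, Birc5 at 4.17), the latter less than the spread between cells. Cell cycle brakes and D-type cyclins differed by 1.31 (SD 0.52), p53 response genes by 1.15 (SD 1.44, 16 of 16; Cdkn1a at 2.62) and ribosome biogenesis genes by 1.09 (SD 0.66, 18 of 20; Odc1 at 2.57, Bop1 at 2.21). Glycolysis genes were 0.92 higher (SD 0.31; Ldha at 1.70), oxidative phosphorylation genes 0.41 (SD 0.17; Cycs at 1.33, Atp5a1 at 1.16), cholesterol synthesis genes 0.75 (SD 0.72) and housekeeping genes 0.53 (SD 0.29). The interferon list differed by -0.19 (SD 0.51), with Gbp2 at -3.43 and Usp18 at 3.21, the immediate early list by 0.46 (SD 0.65) and the TNF list by 0.18 (SD 0.52; Il1b at 22.7 TPM in MK, listed at 0 in NMK). Of the sex-linked list only Xist could be measured, with a difference of -0.40 (SD 1.54), and the RUNX family differed by 0.90 (SD 0.67), with Runx1 at 1.79, Runx3 at 2.34, Runx2 at -0.53 and Cbfb at -0.01. With all 46 libraries, among them 5 failed WT MK libraries, the megakaryocyte-platelet difference was 1.62 and the DNA replication, glycolysis, oxidative phosphorylation, ribosome biogenesis, cholesterol and housekeeping differences turned negative, as did Ldha (-0.48), Atp5a1 (-0.19) and Cycs (-1.63). Within cells without a title prefix the megakaryocyte-platelet difference was 3.02, and in the table without outliers the prefix B1 is left with 1 WT MK and 0 WT NMK cells. Leaving out WT NMK replicate 2 took the DNA replication difference to 0.75, the granulocyte-monocyte one to -0.06, the interferon one to -0.07 and that of Xist to -0.17. Without WT NMK 1A the granulocyte-monocyte and Xist differences were -0.58 and -0.93. Leaving out WT MK B1-1 took p53 response, lymphoid and immediate early genes to 0.67, 0.37 and 0.22. Without WT NMK replicate 1B the RUNX family, TNF and interferon differences were 1.51, 0.33 and -0.31, and without 4A that of TNF was 0.06.

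**Figure D2:**
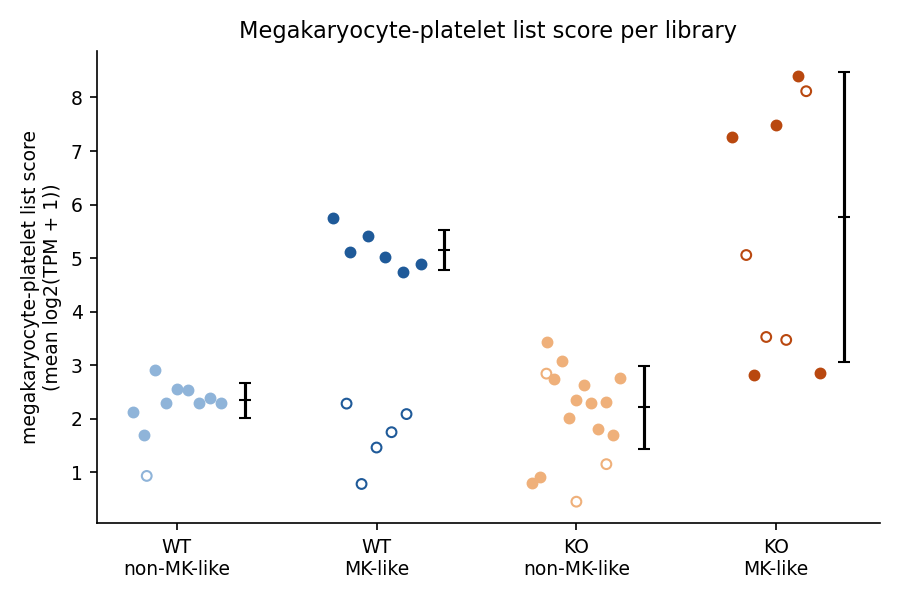
Megakaryocyte-platelet list score (y axis, mean log2(TPM + 1) over all 35 listed genes present in the tables) for each library by group. Filled points are the 33 libraries kept by the authors, hollow points those left out, and black bars the mean and SD of the filled points; the 6 WT MK libraries lie between 4.75 and 5.75, and the KO MK libraries at 2.81, 2.86, 7.25, 7.49 and 8.40.

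The second comparison asked the same of KO cells. KO MK cells also carried far more platelet transcripts than KO NMK cells. They varied more from cell to cell than WT MK cells, whose SD has the limit given above. All 34 measured megakaryocyte-platelet genes were higher in KO MK than in KO NMK cells. The list score was 5.92 ± 2.77 against 2.28 ± 0.80 (SD, n = 5 and 13). Its difference of 3.63 exceeded the SD of 1.55, with 3 of the 5 MK cells above the highest NMK cell. Pf4 averaged 11968 TPM ± 11767 in MK and 208.0 TPM ± 239.8 in NMK cells, and Ppbp, which encodes a platelet chemokine, 7783 TPM ± 10421 and 10.9 TPM ± 36.7. Proliferation genes were not higher in KO MK cells.

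The transcription factor list was 0.87 higher (SD 0.83, 17 of 21) and the platelet genes linked to RUNX1 2.32 higher (SD 1.31, 14 of 14). The cytoskeleton list was 1.78 higher (SD 1.32, 21 of 23) and the granule list 1.78 higher (SD 0.91, 22 of 22), with 5 of 5 MK cells above the highest NMK cell in the latter. Examples are F2rl2 at 5.73, Sdpr at 5.38, Alox12 at 225.2 TPM in MK, listed at 0 in NMK, Gata1 at 5.27, Prkcq at 4.38, Tpm4 at 5.17, Vcl at 3.75, Vps33b at 5.16 and Slc35d3 at 4.26. The 12 genes with the greatest excess were Ppbp (8.09), Hist1h2bc (7.05), Mir7058 (6.50), Alox5 (6.45), Xlr4c (6.42), Fcer1g (6.36), Cst7 (6.19), Clu (6.07), Mir7678 (5.97), Gadd45g (5.82), Slpi (5.81) and Trappc2 (5.76). The 12 with the greatest deficit were Gem (-5.31), Dusp1 (-4.13), Ccdc69 (-3.59), Hist1h1b (-3.41), Ly6a (-3.27), Igfbp4 (-3.26), Fam69b (-3.17), Metrn (-3.16), Hist1h2ae (-3.07), Hist1h4d (-3.05), Neurl1b (14.3 TPM in NMK, listed at 0 in MK) and Hist1h1e (-3.03). Histone genes, Xlr4c, Mir7058 and Mir7678 have near-identical copies or lie inside other genes, so their values are uncertain.

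Stem cell genes differed by 0.60 (SD 0.95, 13 of 24 higher and 11 lower), with Slamf1 at 5.35, Mycn at 5.35 and Pdzk1ip1 at 3.52 but Ly6a lower. The median of the stem cell list stood only at percentile 3.09 of random lists. Erythroid genes differed by 1.48 (SD 1.02, 13 of 16), with Hemgn at 4.29 and Blvrb at 3.65. Granulocyte-monocyte genes differed by 0.67 (SD 1.13), lymphoid genes by 0.93 (SD 1.01), mast cell and basophil genes by 2.98 (SD 1.91) and stromal-endothelial genes by -0.14 (SD 0.76). Mitosis genes differed by -0.01 (SD 1.95, 14 higher and 14 lower), with Top2a at -2.39 and Mki67 at -2.02. DNA replication genes differed by -0.59 (SD 1.66, 22 of 29 lower; Prim1 at -1.43) and ribosome biogenesis genes by -0.17 (SD 1.32). The medians of these 3 lists stood at percentile 0 of random lists, whose own medians were 0.95, 0.98 and 0.98. Housekeeping genes, at a difference of 0.67, also stood low, at percentile 5.05. These percentiles include the 2 failed KO NMK libraries and were not computed without them, so they are no measure of depletion. Brakes and D-type cyclins differed by 0.74 (SD 0.98), p53 response genes by 1.43 (SD 0.99, 16 of 16), with Ccng1 at 4.10 and Fas at 12.5 TPM in MK, listed at 0 in NMK, and interferon genes by 1.10 (SD 0.94, 16 of 21), with Usp18 at 32.1 TPM in MK, listed at 0 in NMK and Rsad2 at 3.25. The remaining lists were higher by 0.12 for immediate early (SD 0.90), 0.73 for TNF (SD 0.68), 0.75 for glycolysis (SD 1.66), 1.15 for oxidative phosphorylation (SD 2.48), 0.95 for cholesterol (SD 1.33), 0.67 for housekeeping (SD 2.07), 0.71 for sex-linked (SD 1.17) and 0.14 for RUNX family genes (SD 1.08), with Runx1 at 1.94, Runx3 at -0.37, Cbfb at -0.97 and Runx2 at -0.04.

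Without the 2 failed KO NMK libraries, an alternative chosen after seeing the data, the megakaryocyte-platelet difference was 3.38 and those of mitosis, DNA replication and ribosome biogenesis were -0.69, -1.31 and -0.71. Those of oxidative phosphorylation, immediate early, housekeeping and RUNX family genes turned to -0.002, -0.12, -0.29 and -0.25 and that of stromal-endothelial genes to 0.01. Glycolysis was left at 0.01, stem cell genes at 0.26, brakes at 0.33, cholesterol at 0.43, sex-linked genes at 0.39, granulocyte-monocyte genes at 0.46, TNF at 0.56, transcription factors at 0.58 and interferon genes at 0.81. Lymphoid genes stood at 0.90, erythroid at 1.18, cytoskeleton at 1.23, p53 response at 1.23, granule at 1.39, RUNX1-linked at 1.89 and mast cell and basophil genes at 2.36, and the median of all genes moved from 0.59 to 0.25. Leaving out KO MK replicate 2 took the granulocyte-monocyte difference to -0.04 and the lymphoid one to 0.46, leaving out B1-4 took TNF and sex-linked genes to 0.43 and 0.47, and leaving out 1A took DNA replication to -0.29. Mitosis genes ranged from -0.46 without KO MK B1-3 to 0.50 without KO MK 1B, and ribosome biogenesis genes stood at 0.04 without 1B. Within the cells without a title prefix the megakaryocyte-platelet, mitosis and DNA replication differences were 4.11, -1.14 and -1.42, and within those with the prefix B1, which hold both failed libraries, 2.93, 1.73 and 0.73, with Top2a at 0.67.

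The third comparison set KO against WT among MK cells, to ask how MK-like cells differ without RUNX1. On average, KO MK cells were higher in interferon response and stem cell genes and lower in ribosome biogenesis and DNA replication genes (n = 5 and 6). Cd48, a surface protein gene on chromosome 1 (171682009 to 171705258), averaged 221.1 TPM ± 250.4 in KO MK cells and was below 1 TPM in all 6 WT MK cells, of which the 95% exact interval reaches 45.9%. The megakaryocyte-platelet list itself differed by 0.61, less than the SD of 1.87, with 3 KO MK cells above and 2 below all WT MK cells. Every KO mean in this comparison, single genes included, pools these 3 and 2 cells.

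Interferon response genes were 1.12 higher (SD 0.49, 17 of 20 members), and all 5 KO cells lay above the highest WT cell. Over all listed genes the score was 3.26 in B1-4 and 2.54 in replicate 2, and 1.76 to 1.91 in the other 3, against 1.19 to 1.38 in WT. Rsad2 differed by 2.95, Ifi47 by 2.94, Gbp2 by 2.48 and Ddx58, which encodes the RNA sensor RIG-I, by 2.42. Stem cell genes were 1.01 higher (SD 0.53, 19 of 22), with Slamf1 at 3.55, Ly6a at 3.06, Procr at 2.23 and Cd34 at 1.99. Only 3 of 5 KO cells lay above the highest WT cell, and over all listed genes the stem cell score was 3.97 in B1-4 and 3.67 in replicate 2, but 2.53 to 2.85 in the other 3 against 2.03 to 2.81 in WT. Platelet genes linked to RUNX1 were 1.14 higher (SD 1.09, 12 of 14), with F13a1 at 2.38 and Rab31 at 2.255 but Pf4 at -2.64, and 3 KO cells lay above and 2 below all WT cells. Pf4 was 65.8 TPM in B1-4 and 213.7 TPM in replicate 2. In the other 3 KO cells it was 13752 to 26885 TPM, against 12513 to 19619 TPM in WT. Granule genes were 0.61 higher (SD 0.44, 18 of 22; Vps33b at 2.14, Rab32 at 1.74, Snap23 at 1.56), and cytoskeleton genes 0.48 (SD 0.67, 17 of 23; Zyx at 1.59, Arpc5 at 1.14). In the megakaryocyte-platelet list, 24 of 34 members were higher, such as Thbs1 at 2.98 and Gp6 at 2.48. The transcription factor list differed by 0.06 (SD 0.60), although Nfe2 was higher by 1.41, Gfi1b by 1.30 and Meis1 by 0.96. The medians of the interferon, stem cell and RUNX1-linked lists stood at percentile 100 of random lists. High percentiles were not particular to them. The TNF, megakaryocyte-platelet, cytoskeleton, granulocyte-monocyte and granule lists stood at 99.7, 99.7, 99.5, 99.3 and 99.1. Of these, all but the granule list had differences smaller than their SD.

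Ribosome biogenesis genes were lower on average, with a difference of -1.02 (SD 0.50, 19 of 20 lower). Only 2 of 5 KO cells lay below the lowest WT cell, with scores of 4.42 to 5.69 in KO against 5.37 to 6.60 in WT. KO MK B1-3 and B1-4, at 5.69 and 5.62, lay above that lowest cell, B1-1, the only WT MK cell with their prefix. Npm1, the nucleolar protein gene, averaged 480.1 TPM ± 241.1 in KO and 1256 TPM ± 253.3 in WT MK cells, and Mrto4 differed by -1.91 and Nop58 by -1.44. DNA replication genes differed by -0.76 (SD 0.71, 27 of 29 lower; Dut at -1.95) and oxidative phosphorylation genes by -0.25 (SD 0.18; Cycs at -1.48, Atp5o at -0.65). With all 46 libraries the oxidative phosphorylation difference turned to 0.91, and Atp5o to 1.17. Mitosis genes differed by 0.15 (SD 1.10, -0.31 without KO MK B1-3 and 0.66 without KO MK 1B; Mki67 at -1.44). The 12 genes with the greatest deficit in KO MK cells were Tsix (95.2 TPM in WT, listed at 0 in KO), Snord100 (57.6 TPM in WT, listed at 0 in KO), Snora73b (-4.70), Snord12 (41.9 TPM in WT, listed at 0 in KO), Snord42b (-4.32), Snora24 (29.0 TPM in WT, listed at 0 in KO), Arxes2 (-4.25), Bex4 (-4.03), Ms4a3 (-4.01), Snord33 (17.8 TPM in WT, listed at 0 in KO), Snhg4 (-3.94) and Snord58b (24.2 TPM in WT, listed at 0 in KO). Of these, 7 are small nucleolar RNA genes inside other genes and Tsix overlaps Xist, and whether the counting used strand is not given in the sources used here, so these values are uncertain. The 12 with the greatest excess were Cd48 (6.64), Glipr2 (6.02), Xlr4c (5.61), Mir7678 (4.87), Slpi (4.81), Alox12 (4.63), Cd200r1 (4.50), Il2rg (4.47), Ptgir (4.29), Ncf4 (4.11), Col4a2 (3.93) and Tnfaip8l2 (3.93).

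Of the other lists, erythroid genes differed by 0.20 (SD 0.68, -0.06 without KO MK 1B and 0.63 without B1-4; Icam4 at -3.30), granulocyte-monocyte genes by 0.86 (SD 1.38; Tyrobp at 3.36, Lyz2 at 1.93), lymphoid genes by 0.69 (SD 1.87), mast cell and basophil genes by -0.13 (SD 0.89, 0.31 without WT MK B1-1) and stromal-endothelial genes by -0.60 (SD 0.50). Brakes and D-type cyclins differed by -0.04 (SD 0.43; Cdk6 at -1.23), p53 response genes by 0.08 (SD 1.26, -0.23 without KO MK B1-4 and 0.57 without WT MK B1-1), immediate early genes by 0.08 (SD 0.51), TNF genes by 0.40 (SD 0.62), glycolysis genes by 0.10 (SD 0.30), cholesterol genes by 0.03 (SD 0.68; Insig1 at 1.86), housekeeping genes by 0.06 (SD 0.28) and RUNX family genes by -0.07 (SD 0.56). Leaving out KO MK replicate 1B took the megakaryocyte-platelet difference to -0.06, that of the RUNX1-linked genes to 0.70 and that of cytoskeleton genes to 0.26, leaving out 1A took DNA replication to -0.47, leaving out 2 took granulocyte-monocyte and lymphoid genes to 0.14 and -0.18, and leaving out B1-4 took TNF and oxidative phosphorylation genes to 0.04 and -0.15. The small differences of transcription factor, brake, immediate early, glycolysis, cholesterol, housekeeping and RUNX family genes also turned sign when 1 library was left out. Within cells without a title prefix the interferon, stem cell and ribosome biogenesis differences were 0.94, 1.08 and -1.47. There the megakaryocyte-platelet difference was 1.22 and that of mitosis genes turned to -0.69. In the table without outliers the prefix B1 is left with 1 WT MK cell.

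Sex-linked genes separated the genotypes. Xist, the transcript of the inactive X chromosome in females, was at 1 TPM or more in 6 of 6 WT MK and 8 of 9 WT NMK cells in 0 of 5 KO MK cells and in 1 of 13 KO NMK cells, the failed B1-2a. The sum of 4 Y-linked genes reached 1 TPM in 5 of 5 KO MK and 10 of 13 KO NMK cells and in 0 WT cells. In MK cells Ddx3y averaged 10.2 TPM ± 8.15 in KO and was listed at 0 in WT, and Eif2s3y averaged 13.9 TPM ± 10.1 in KO and was listed at 0 in WT. The sex-linked list differed by 0.90 (SD 0.39). Apart from WT NMK 1A and KO NMK 4A, B1-1b and B1-2a, the difference between KO and WT is therefore also one between libraries with Y-linked transcripts and libraries with Xist.

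**Figure D3:**
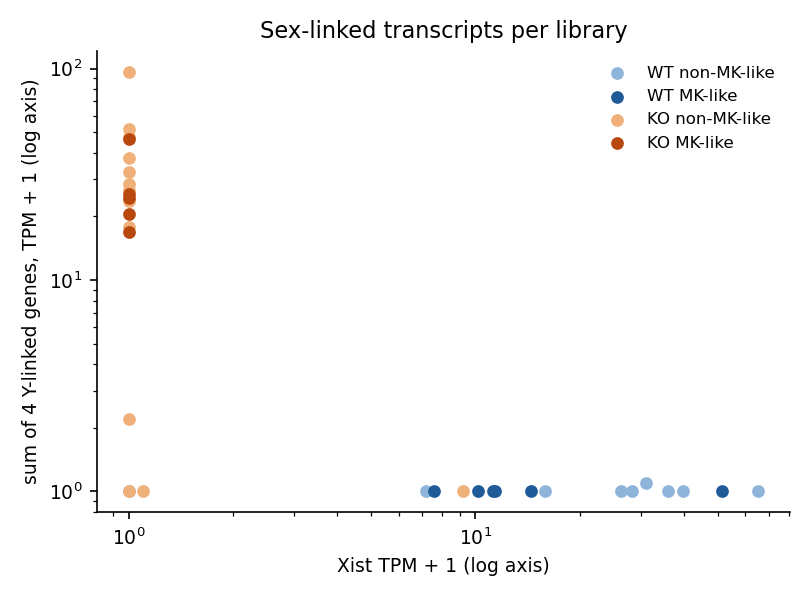
Xist (x axis, TPM + 1, log axis) against the sum of 4 Y-linked genes (y axis, TPM + 1, log axis) for 33 libraries. WT libraries lie along the x axis and KO libraries along the y axis, except the failed KO NMK replicate B1-2a, at 8.2 TPM of Xist, and 3 libraries under 1 TPM for both, WT NMK 1A and KO NMK 4A and B1-1b.

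**Figure D4:**
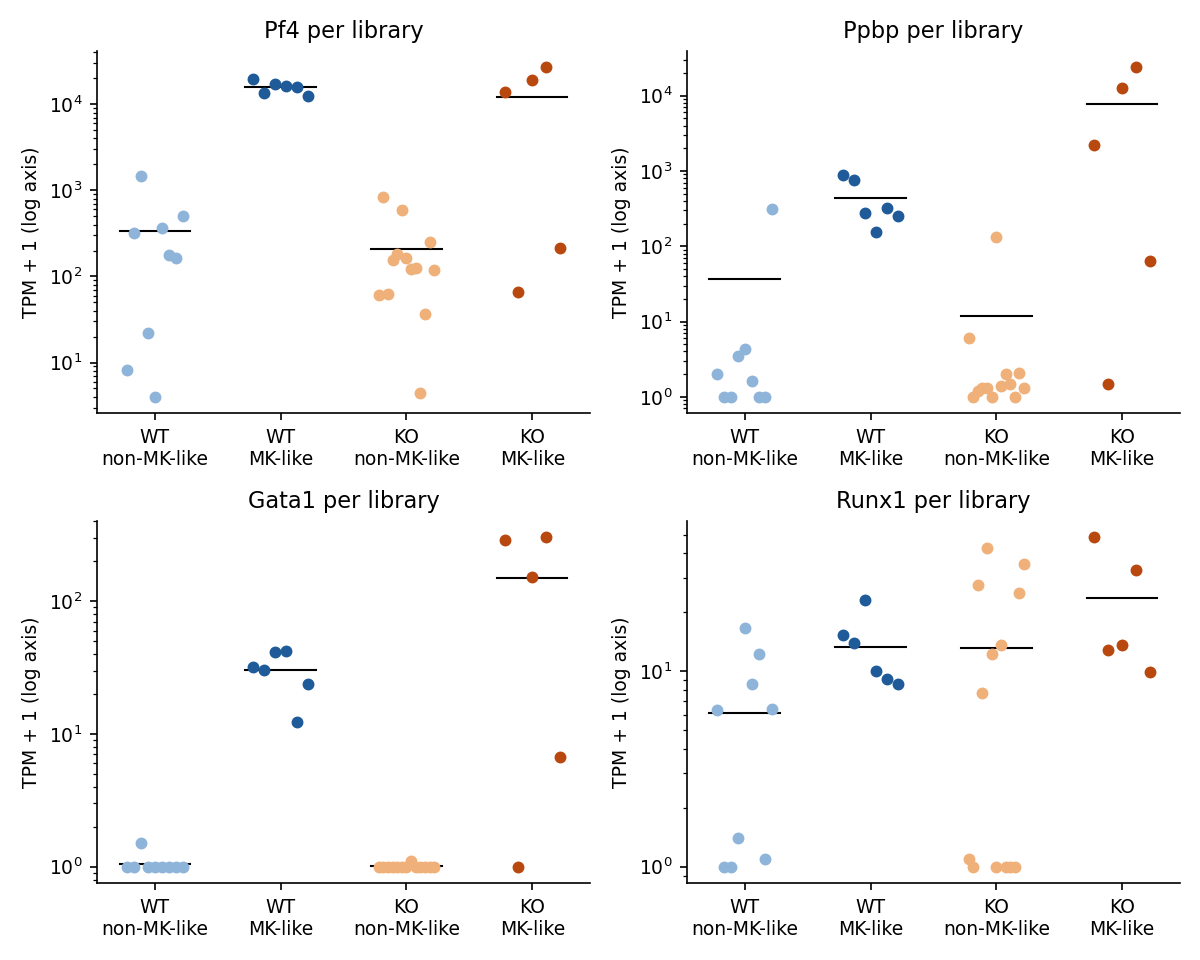
Pf4, Ppbp, Gata1 and Runx1 (y axes, TPM + 1, log axes) in each of the 33 libraries by group, with a line at the mean TPM of the group. In 2 of the 5 KO MK libraries Pf4 was 65.8 and 213.7 TPM, against 12513 to 19619 TPM in WT MK libraries.

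The fourth comparison set KO against WT among NMK cells. KO NMK cells were on average higher in genes of cell division, with 27 of 28 mitosis genes and 25 of 29 DNA replication genes above their WT mean (n = 13 and 9). Mitosis scores of WT cells were either 0.42 to 1.44 or 4.44 to 5.24. Those of KO cells other than the 2 failed libraries were 2.01 to 6.77, so the higher WT scores lay within the KO range. Top2a, which untangles DNA in dividing cells, averaged 103.0 TPM ± 58.9 in KO and 34.1 TPM ± 57.0 in WT NMK cells. Both list differences, 1.79 (SD 2.10) and 0.96 (SD 1.62), were smaller than the spread between cells, and both medians stood at percentile 100 of random lists. High percentiles were not particular to cell division. Housekeeping genes stood at 99.35 with a difference of -0.07, ribosome biogenesis genes at 98.2 and brakes at 97.1. These percentiles include the 2 failed KO NMK libraries and were not computed without them. Cd48 again averaged 95.4 TPM ± 94.8 in KO cells and was listed at 0 in all 9 WT cells. Megakaryocyte-platelet genes hardly differed, at -0.15 (SD 0.84).

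Among division genes, Birc5 differed by 3.38, Aurkb by 3.14, Ccne1 by 2.69, Rrm1 by 1.95 and Fen1 by 1.88, and brakes and D-type cyclins differed by 0.48 (SD 0.93; Cdkn2c at 3.07, Ccnd3 at 1.45). The 12 genes with the greatest excess were Cd48 (95.4 TPM in KO, listed at 0 in WT), Fbxo5 (4.45), Mir6924 (4.31), Cdca5 (4.22), Mir6939 (3.96), Mir6951 (3.62), Kif11 (3.58), Mir6904 (41.4 TPM in KO, listed at 0 in WT), Ndrg1 (3.40), Mthfd2 (3.36), Mir7053 (3.30) and Tor3a (3.21). Of these, Fbxo5, Cdca5 and Kif11 act in cell division, and the 5 microRNA genes are uncertain for the reason given above. The 12 with the greatest deficit were Tsix (-6.26), Bex4 (-5.11), Serf1 (-4.75), Ndn (81.5 TPM in WT, listed at 0 in KO), Ccdc28b (-4.52), Rgcc (-4.36), Rprm (46.9 TPM in WT, listed at 0 in KO), Fkbp11 (-4.06), Snhg3 (-3.97), Xist (-3.95), Tmem126b (-3.71) and Selm (-3.70).

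Transcription factor genes differed by 0.32 (SD 0.74; Gata2 at 1.79), platelet genes linked to RUNX1 by 0.44 (SD 0.95; Rab31 at 1.71), cytoskeleton genes by 0.13 (SD 1.17; Tuba8 at 2.92) and granule genes by -0.03 (SD 0.83), and the platelet tetraspanin gene Cd9 was lower by -2.51. Stem cell genes differed by -0.46 (SD 0.90; Pdzk1ip1 at -2.91), erythroid genes by 0.17 (SD 1.12), granulocyte-monocyte genes by -0.07 (SD 0.91), lymphoid genes by -0.13 (SD 0.87), mast cell and basophil genes by 0.61 (SD 2.06) and stromal-endothelial genes by 0.09 (SD 0.55). Interferon genes differed by -0.15 (SD 0.93; Gbp2 at -3.06), p53 response genes by -0.20 (SD 1.23; Fas at 25.7 TPM in WT, listed at 0 in KO, Ccng1 at -2.16), immediate early genes by 0.37 (SD 0.91) and TNF genes by -0.22 (SD 0.71). Glycolysis genes differed by 0.27 (SD 1.496; Hk1 at 1.58), oxidative phosphorylation genes by -0.996 (SD 2.22; Cox6c at -2.47, Ndufa2 at -2.04), ribosome biogenesis genes by 0.23 (SD 1.25), cholesterol genes by -0.14 (SD 1.25), housekeeping genes by -0.07 (SD 1.86; Polr2a at 2.11), sex-linked genes by 0.27 (SD 0.94; Ddx3y at 2.77) and RUNX family genes by 0.69 (SD 1.04; Runx3 at 1.16, Cbfb at 0.90, Runx2 at 0.22). Without the 2 failed KO NMK libraries the mitosis and DNA replication differences were 2.48 and 1.68, the oxidative phosphorylation difference was 0.16 and the megakaryocyte-platelet difference 0.18. Housekeeping and glycolysis differences were then 0.89 and 1.01, with 10 and 9 of the 13 KO cells above the highest WT cell, and those of ribosome biogenesis, cytoskeleton, granule and RUNX family genes were 0.78, 0.71, 0.37 and 1.08. Transcription factors stood at 0.63, RUNX1-linked genes at 0.88, brakes at 0.89, mast cell and basophil genes at 1.23, erythroid at 0.53, immediate early at 0.64 and sex-linked genes at 0.48. Cholesterol, granulocyte-monocyte, interferon and p53 response genes turned to 0.38, 0.17, 0.16 and 0.01, stromal-endothelial genes to -0.03, and stem cell, lymphoid and TNF genes were at -0.14, -0.10 and -0.03. Only cells without a title prefix could be compared within a prefix, and their mitosis and DNA replication differences were 2.03 and 1.76. Leaving out WT NMK replicate 2 took the DNA replication difference to 0.58, leaving out KO NMK 1B took that of mast cell and basophil genes to 0.34, and leaving out WT NMK 1A took ribosome biogenesis and sex-linked genes to 0.02 and 0.10. The differences of megakaryocyte-platelet, granule, erythroid, granulocyte-monocyte, lymphoid, stromal-endothelial, p53 response, cholesterol and housekeeping genes turned sign when 1 library was left out.

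Setting the MK to NMK difference of KO against that of WT, over the 34 megakaryocyte-platelet genes measured in any group, gave 3.63 in KO and 2.89 in WT. The difference between them, 0.74, was smaller than the SD between cells of 1.46, was 0.07 without KO MK 1B and was not tested. For DNA replication the same value was -1.73 (SD 1.22), for mitosis -1.64 (SD 1.69), for ribosome biogenesis -1.25 (SD 0.91), for stem cell genes 1.32 (SD 0.72) and for interferon response genes 1.21 (SD 0.67). Without the 2 failed libraries these 6 values were 0.49, -2.44, -2.33, -1.80, 1.001 and 0.92. Across genes, which are not independent replicates, the MK to NMK differences of WT and KO correlated with r = 0.38 (rho = 0.30, 10728 genes). Those between KO and WT in MK and in NMK cells correlated with r = 0.088 (rho = 0.080, 10432 genes).

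**Figure D5:**
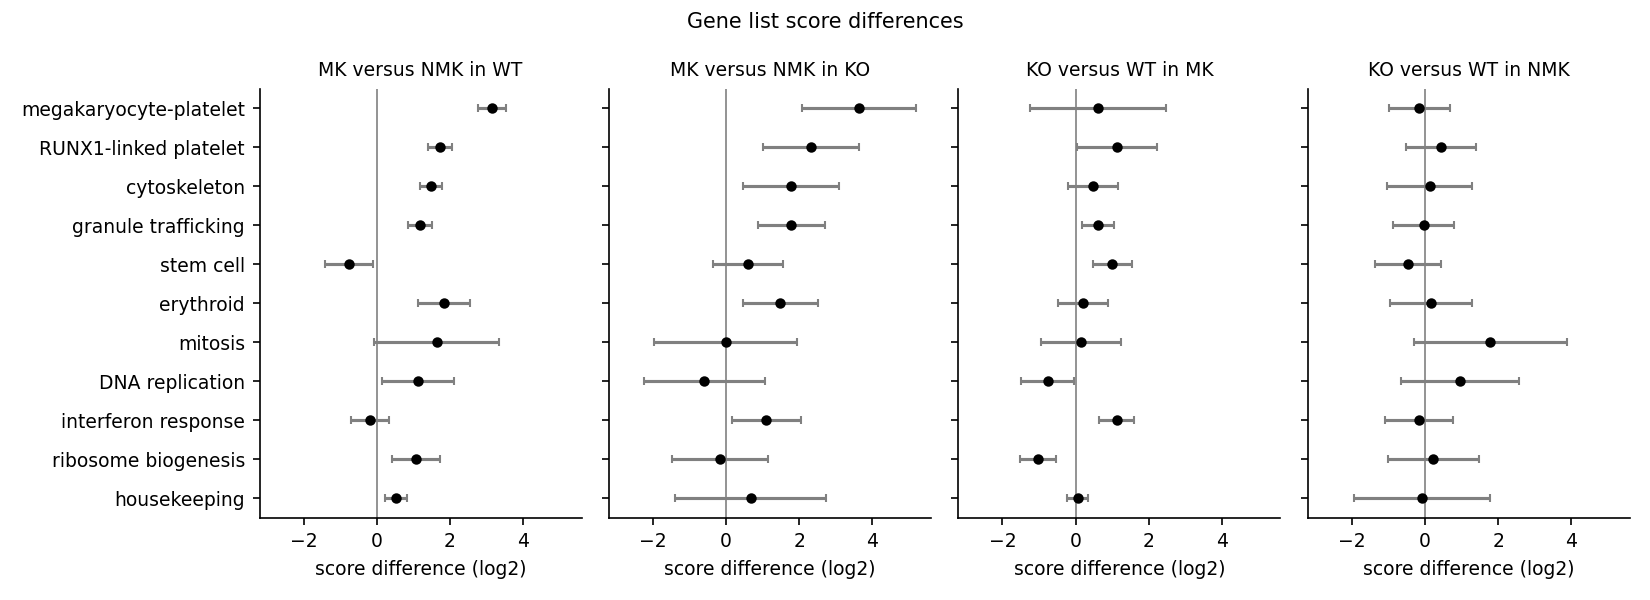
Score differences (x axes, log2(TPM + 1) units) of 11 gene lists in the 4 comparisons, with bars for the pooled SD between cells. The megakaryocyte-platelet difference is 3.16 and 3.63 for MK against NMK cells in WT and KO, and 0.61 and -0.15 for KO against WT in MK and NMK cells.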

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

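The test of whether similar libraries came from the same cDNA was fixed before its result was seen, and the other test below, on the number of detected genes, only after. For each group of 4 to 10 libraries, the gap of the extreme library to its neighbour was divided by the range of the group and set against the 95% critical value of Dixon. Chance exceeds it in about 1 of 20 groups. It was exceeded for 11 of 75 list scores (14.7%) and 54 of 314 values of named genes (17.2%), many of which are at or near 0 in all libraries but 1, where the ratio is 1.

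Among list scores in WT MK cells, the extremes and their ratios were mast cell (highest, replicate B1-1, 0.711), immediate early (highest, replicate B1-1, 0.721), ribosome biogenesis (lowest, replicate B1-1, 0.639), sex-linked (highest, replicate B1-1, 0.662), interferon (lowest, replicate 1B, 0.657) and glycolysis (lowest, replicate 2, 0.64). In WT NMK cells they were DNA replication (lowest, replicate 2, 0.715), cell cycle brake (highest, replicate 3, 0.497) and cholesterol (lowest, replicate 3A, 0.512), and in KO MK cells immediate early (lowest, replicate 2, 0.834) and TNF (highest, replicate B1-4, 0.719).

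Single genes gave further extremes in WT MK cells, with the ratio after each gene. Replicate 1A was lowest for Snord12 (0.757) and highest for Ly6a (1), Lgals1 (0.739) and Ptgir (0.685). Replicate 1 was highest for Krt18 (0.655) and Cd48 (1). Replicate 4 was highest for Ramp1 (0.648) and Col4a2 (0.637). Replicate 2 was lowest for Fcer1g (0.773) and Insig1 (0.632). Replicate B1-1 was lowest for Ccnb2 (0.748), Cycs (0.662), Usp18 (0.692), Bex4 (0.651), Snord58b (0.64), Hspe1 (0.685) and Mrto4 (0.772) and highest for Tyrobp (1) and Xist (0.662).

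In WT NMK cells the genes were as follows. Replicate 3A was lowest for Ly6a (0.676), Spi1 (0.58) and Ccdc28b (0.608). Replicate 4A was lowest for Cd24a (0.652), Krt18 (0.669), Ldhb (0.564) and Vim (0.858) and highest for Ccl2 (1), Gp5 (0.957) and Ms4a3 (1). Replicate 4B was highest for Ppbp (0.746). Replicate 3 was highest for Zswim7 (0.81), Rasl11a (1), Slc35d3 (0.945), Mir6951 (1) and Mir7053 (1). Replicate 2 was lowest for Rrm1 (0.627) and highest for Timp3 (0.788). Replicate 1B was highest for Mrps22 (0.757), Runx2 (0.566) and Gata1 (1). Replicate 1A was lowest for Tsix (0.635). Replicate 1 was lowest for Serf1 (0.566) and highest for Ddx3y (1).

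Among KO MK cells the same was seen for fewer genes. Replicate B1-4 was lowest for Hemgn (0.713) and Cycs (0.714) and highest for Gem (1), Fam69b (1) and Runx2 (0.806). Replicate 2 was highest for Dusp1 (1) and Hist1h1b (0.903). Replicate B1-3 was lowest for Eif2s3y (0.728) and highest for Snora73b (1) and Snord42b (1). Replicate 1B was highest for Bex4 (0.899).

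Some MK libraries the authors left out carried platelet transcripts above the highest NMK library of their genotype that was kept. Those highest values were 1453 TPM of Pf4 in WT and 841.3 TPM in KO NMK, and 313.8 TPM of Ppbp in WT and 133 TPM in KO NMK libraries. Pf4 was 4426 TPM in WT MK B1-2 and 3471 TPM in WT MK B1-2b, but 1035 TPM in B1-1a, 494.1 TPM in B1-1b and 441.1 TPM in B1-2a, and Ppbp was 24.8 TPM or lower in all 5 left-out WT MK libraries. In left-out KO MK libraries it was 1602 TPM in B1-1b, 3625 TPM in B1-1, 2705 TPM in B1-1a and 43254 TPM in 1. Ppbp was 736.1, 3824, 730.7 and 15643 TPM in the same 4 libraries.

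The 5 WT MK libraries without a title prefix resembled each other far more than other cells did, with r from 0.9505 to 0.971 across genes, and B1-1 stood apart from them. The same cDNA deposited several times may account for this, and stays open, since 30 of 1461 genes with a mean of 100 TPM or more differed 4-fold or more between these 5 libraries, short of the 50 set in advance to exclude it. The same cDNA was set in advance to leave no such gene, so neither outcome was met. The number of detected genes could also raise r, and the pairs below do not decide whether it is the only cause. Among 11 other pairs of 1 group with 12000 genes or more in both libraries, r was 0.629 to 0.902, below every pair of the 5. The values below 0.876 all involve KO MK B1-4. B1-1 held 15238 genes above 0 and the 5 held 14089 to 15252, yet its r with them was 0.876 to 0.902. That contrast rests on 1 library with another title prefix, so whether the number of genes sets r stays open. A biological likeness of these cells was not tested.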

How the results depend on the processing

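The 2 settings that use a housekeeping score of 6 were chosen only after seeing the data, and the others before the data were examined. Of 1325 alternative values of list differences, 1226 moved by less than the SD between cells, 89 by more with no turn of sign of a difference larger than its SD, and 10 turned such a sign. For single named genes these counts were 2632, 276 and 6 of 2914, and all 26 values of Runx1 in KO against WT moved by less than the SD. Some settings cannot move a value, such as a filter on low values for a single gene. A large SD, as in comparisons that hold the failed KO NMK libraries, also lets large shifts count as small. These counts therefore do not measure how stable the values are. The megakaryocyte-platelet difference ranged over the alternatives from 1.62 to 4.66 in WT, from 2.26 to 5.09 in KO, from 0.42 to 2.25 for KO against WT in MK cells and from -0.35 to 0.29 in NMK cells. With each library left out in turn these ranges were 3.07 to 3.25, 2.96 to 4.29, -0.06 to 1.35 and -0.28 to 0.01, and the difference between KO and WT in the MK to NMK difference ranged from 0.07 to 1.47. The lowest value for KO against WT in MK cells came without KO MK replicate 1B, and the highest in NMK cells without KO NMK replicate B1-1b. Leaving out KO MK replicate B1-4 took the TNF difference of KO MK against NMK cells to 0.43 and the oxidative phosphorylation difference of KO against WT MK cells to -0.15. Median-ratio rescaling took the median difference of all genes in the 4 comparisons to 0.60, 0.53, 0.08 and 0.16, and all 46 libraries took it to 0.01, 0.05, 0.29 and 0.23. Prefix B1 gave no value against or within WT, for which it holds 1 MK and 0 NMK libraries in the table without outliers. The alternative without cells of few detected genes left out 1 cell, KO NMK B1-2a. No paired analysis was possible because no label ties cells with the same number to an animal or culture and no result comes from a test. TPM keeps no depth, so how depth limits low values is unknown.

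With all 46 libraries, MK against NMK in WT, values moved to 1.62 for megakaryocyte-platelet, 0.29 for transcription factor, 0.62 for RUNX1-linked, 0.060 for cytoskeleton, 0.0017 for granule, 0.33 for erythroid, 1.40 for mast cell, 0.043 for cell cycle brake, -0.83 for interferon, -0.27 for immediate early, -0.39 for TNF and 0.19 for RUNX family. KO against WT in MK moved to 1.27 for cytoskeleton, 0.94 for erythroid, 0.49 for cell cycle brake, 0.78 for glycolysis, 0.78 for housekeeping and 0.43 for sex-linked. The sign turned for MK against NMK in WT, to -0.49 for DNA replication, -0.68 for glycolysis, -2.01 for oxidative phosphorylation, -0.32 for ribosome biogenesis, -0.56 for cholesterol, -1.18 for housekeeping, -0.48 for Ldha, -1.30 for Gapdh, -0.19 for Atp5a1 and -1.63 for Cycs. The sign turned for KO against WT in MK, to 0.036 for stromal, 0.91 for oxidative phosphorylation and 1.17 for Atp5o. With all libraries at a housekeeping score of 6 or more, MK against NMK in KO, values moved to -1.49 for ribosome biogenesis. In turn, KO against WT in MK moved to -0.47 for oxidative phosphorylation and -1.73 for ribosome biogenesis. With members at a mean TPM of 10 or more, MK against NMK in WT, values moved to 1.65 for transcription factor, 0.061 for stromal and -0.34 for TNF. MK against NMK in KO moved to 2.02 for lymphoid. The sign turned for KO against WT in MK, to 0.33 for stromal. With no filter on low values, MK against NMK in WT, values moved to 0.93 for erythroid and 0.90 for mast cell. MK against NMK in KO moved to 0.66 for mast cell. With a pseudocount of 0.1, MK against NMK in WT, values moved to 4.66 for megakaryocyte-platelet, 2.11 for transcription factor, 2.53 for RUNX1-linked, 2.00 for cytoskeleton, 2.31 for granule, 3.25 for erythroid, 1.96 for lymphoid, 4.54 for mast cell, 2.45 for stromal, 2.30 for cell cycle brake, 1.09 for TNF and 1.28 for glycolysis. Values moved for MK against NMK in KO to 2.94 for granule, 2.26 for interferon, 2.54 for p53 and 1.53 for TNF. KO against WT in MK moved to -1.78 for stromal, 1.63 for interferon and 2.03 for sex-linked. With a pseudocount of 10, MK against NMK in WT, values moved to 1.72 for megakaryocyte-platelet, 0.41 for transcription factor, 1.004 for RUNX1-linked, 0.92 for cytoskeleton, 0.40 for granule, 0.69 for erythroid, 0.046 for stromal, 0.54 for cell cycle brake and 0.60 for glycolysis. Values moved for MK against NMK in KO to 0.84 for granule. KO against WT in MK moved to -0.049 for stromal, 0.51 for interferon and 0.24 for sex-linked. As the ratio of mean TPM, MK against NMK in WT, values moved to 2.50 for megakaryocyte-platelet, 0.74 for transcription factor, 1.11 for RUNX1-linked, 0.99 for cytoskeleton, 0.65 for granule, -1.59 for stem cell, 0.91 for erythroid, -1.98 for granulocyte-monocyte, -1.70 for lymphoid, 0.36 for cell cycle brake, -1.18 for interferon, -0.38 for immediate early, -0.77 for TNF and 0.18 for RUNX family. Values moved for MK against NMK in KO to 0.21 for erythroid, -1.72 for stromal and -1.39 for immediate early. KO against WT in MK moved to 1.76 for stem cell, 2.49 for granulocyte-monocyte, 2.58 for lymphoid, 1.65 for interferon and 1.30 for TNF. In turn, KO against WT in NMK moved to 1.68 for erythroid, 0.85 for stromal and 1.32 for immediate early. The sign turned for MK against NMK in WT, to -0.0045 for stromal. As medians over cells, MK against NMK in KO, values moved to -0.47 for granulocyte-monocyte. The difference between KO and WT in the megakaryocyte-platelet difference was 2.24 there. Within the title prefix B1, MK against NMK in KO, values moved to 1.76 for cell cycle brake, 2.62 for p53 and 1.44 for ribosome biogenesis. The sign turned for MK against NMK in KO, to 0.67 for Top2a. The cause of these shifts was not tested, apart from the pseudocounts, which by construction set how much low values count.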

Other observations

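All tests in this part were chosen only after the results were seen. Cd48 was the only gene among the 12 with the greatest excess for KO against WT in both MK and NMK cells, and Tsix and Bex4 were the only ones among the 12 with the greatest deficit in both. Cd48 reached 1 TPM in 5 of 5 KO MK and 11 of 13 KO NMK cells and in 0 WT cells. For MK against NMK cells, Fcer1g and Ppbp were among the 12 with the greatest excess in both genotypes, and Ly6a among the 12 with the greatest deficit in both. The left-out library KO MK 1 had a housekeeping score of 7.99, a megakaryocyte-platelet score of 8.12 over all listed genes and a mitosis score of 0.12.

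Gene differences between KO and WT libraries could reflect the sex of the mice. Xist was seen in 14 of 15 sound WT libraries and Y-linked genes in 15 of 16 sound KO libraries, sound meaning kept by the authors and with a housekeeping score of 6 or more. The number of sound libraries of the other sex within a genotype was 0, so sex and genotype cannot be told apart. Single libraries swapped between WT and KO are argued against, since 0 sound libraries carried the sex marker of the other genotype. Loss of RUNX1 stays open as the biological explanation.

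Within KO MK, 2 libraries had megakaryocyte-platelet scores of 2.81 (B1-4) and 2.86 (replicate 2), over all listed genes, against 7.25 to 8.40 in the other 3. Failed libraries are argued against by the lower of their housekeeping scores, 8.68, and by mitochondrial shares of 8.67% and 10%. Labels swapped between KO MK and KO NMK are argued against by the highest KO NMK score, 3.43, which lies below all of the other 3. Single wrong labels without a partner, cells picked by looks that lack the transcripts, and a mixed response to loss of RUNX1 may each remain, and were not tested.

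Titles that share a number and differ in the letter A or B were tested as a hint that the letters mark 2 cells more alike than other cells of the group. Of 7 such pairs, 1 holds a failed library, and 4 of the other 6 had a higher r than the median pair of their group, which leaves it open.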
